A study of Chrysodeixis includens with 4 samples.

How the data were processed

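Total RNA from heads and bodies of third-instar Chrysodeixis includens larvae was extracted with Trizol, and libraries were made from 1 ug with an Illumina TruSeq RNA kit, per the labels' protocols. Head and body were sequenced as 2 libraries each, from pools of 5 larvae, per the series' design text. TopHat and Cufflinks were named in the submitters' processing notes, without versions. Contig names in the table are those of the assembler Trinity, per the file's locus column. Aligner settings, annotation and normalization between tissues are not given in the sources used here.

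One table was used. Its columns follow the gene-level output of the Cuffdiff program of Cufflinks, per the file headers. It lists for each locus the authors' FPKM (fragments scaled to transcript length and to sequencing depth) in head and in body, a log2 ratio, a test statistic or score, and the authors' p-value and q-value. The columns headed Head and Body hold the group codes of the 2 values, and the values were assigned to the tissues in that order. No named gene was available to check this assignment, so every direction rests on it. The deposited log2 fold is body over head and matched the FPKM values to within 0.0016. It was not used, because 951 of its cells, all of loci listed at 0 in body, hold spreadsheet error text in place of a negative infinite value, and 1349 read as infinite. Folds were recomputed from the FPKM values. The authors' deposited p-values have a smallest value of 5e-05, which 2327 loci share. All called loci have a q under 0.05, up to 0.0499, and q recomputed by the Benjamini-Hochberg method over the 19061 tested loci differed from the deposited q by at most 5.2e-07. The authors did not test 817 loci, whose FPKM was at most 7.13 in head and 6.80 in body. The lowest FPKM in the higher tissue of a tested locus was 3.03. Locus starts count from 0 in the file and are given from 1 here.

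Because the table holds 1 value per tissue, no test between tissues was added, and calls are those of the authors at a q of 0.05. The design fixed before the data were examined was a model on values per library, if the table gave them, and otherwise the authors' q. Differences are log2((head FPKM + 1)/(body FPKM + 1)), where the pseudocount of 1 shrinks the change of low loci. Plain ratios of FPKM are given as folds only for loci above 0 in both tissues. Gene lists for tissues of a caterpillar had been fixed for matching to annotation text, and none could be applied because no locus carries a name. The loci named in the text follow a rule fixed before the data were examined for a table without protein names. It takes the 2 identifiers per direction with the largest fold among called loci above 0 in both tissues, with 10 FPKM or more in the higher one.

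Fragment steps were estimated after the data were seen. For loci of 600 bases or more, FPKM × (length − offset)/1000 was computed, with the offset (202 bases in head, 201 in body) chosen for the sharpest histogram, and the 2 lowest peaks were taken as the worth of 1 fragment in each library. Values within 1% of a step or of a sum of 2 steps were assigned 1 or 2 fragments. The relative depth is the ratio of the summed inverse steps, after whatever scaling the authors applied. The expected number of fragments at the level of the other tissue assumes that a tissue value is the mean of its 2 libraries. Exact binomial (Clopper-Pearson) 95% intervals treat loci as independent, and these intervals and the floor of 3 fragments cover counting error only. Depth as a number of reads stays unknown. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

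The procedures were tested on simulated data made from the real loci. With 200 changes planted among 19878 loci, all 200 were recovered by the adjustment of p-values, with 13 false calls. The planted loci were given very small p-values directly, so their recovery was fixed in advance. It checks the arithmetic of the adjustment only, and not the detection of expression changes. Simulated pairs of libraries of known depth gave back their fragment steps, and 100.0% of the 1126 loci in a deeper set and the 1766 loci in a shallower set that were assigned 1 or 2 fragments were assigned the right number. These simulated values were exact means of whole fragment counts, so they lay on steps by construction. They check the arithmetic of the assignment, and not whether the real values arose in that way. Alternatives were a stricter q, a filter on low values, a minimum fold, leaving out loci listed at 0, other pseudocounts and, for folds, other scalings, all chosen before the data were examined. A minimum length of 500 bases, 1 locus per Trinity gene, other limits of fold and level for the loci not called, equal upper quartiles for those loci and for loci restricted to one tissue, and other scalings for the direction of calls were added after seeing the data.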

Results

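Expression was measured by RNA sequencing in third-instar larvae of Chrysodeixis includens, the soybean looper, a noctuid moth whose caterpillars feed on soybean and other crops. Larvae were dissected into head and body. The head carries the brain, eyes, antennae and mouthparts, and the body holds the gut, fat body, Malpighian tubules and most of the muscle. Each tissue was sequenced as 2 replicate libraries, each from a pool of 5 larvae, which gives 4 libraries in all. The comparison the design implies is head against body, and it asks which transcribed loci differ between these parts of the caterpillar. The authors' deposited table gives 1 FPKM value per tissue for each of 19878 loci on contigs of a de novo assembly, with their p and q. No value per library was analysed here, so no SD or n accompanies the values below, and no spread between replicates could be computed. The p-values of that table rest on 2 replicates per tissue, and the labels do not say whether the 2 pools were independent, so they may measure technical spread. The table pairs 0 of the loci with a gene name, so loci are described by identifier, level and grouping, and gene functions are not given. Every direction below rests on the column order of that table, which could not be checked against a gene of known tissue.

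The depth of the libraries is not stated, but low values showed the size of 1 sequenced fragment. In loci of 600 bases or more, FPKM multiplied by locus length less about 200 bases fell on discrete steps. The lowest steps in head lay at 0.0882 and 0.119 FPKM·kb, and those in body at 0.210 and 0.226 FPKM·kb, which is 1 fragment in either of the 2 libraries of the tissue. Of the 445 head values low enough to hold at most 2 fragments, 96.2% lay within 1% of a step, whereas the windows around the steps cover 6.89% of that range. In body this held for 97.5% of 517 values, with 7.65% of the range covered. A smaller step means a deeper library. On the deposited scale, head libraries together were 2.15 times as deep as body libraries, so low levels were resolved more finely in head.

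**Figure D1:**
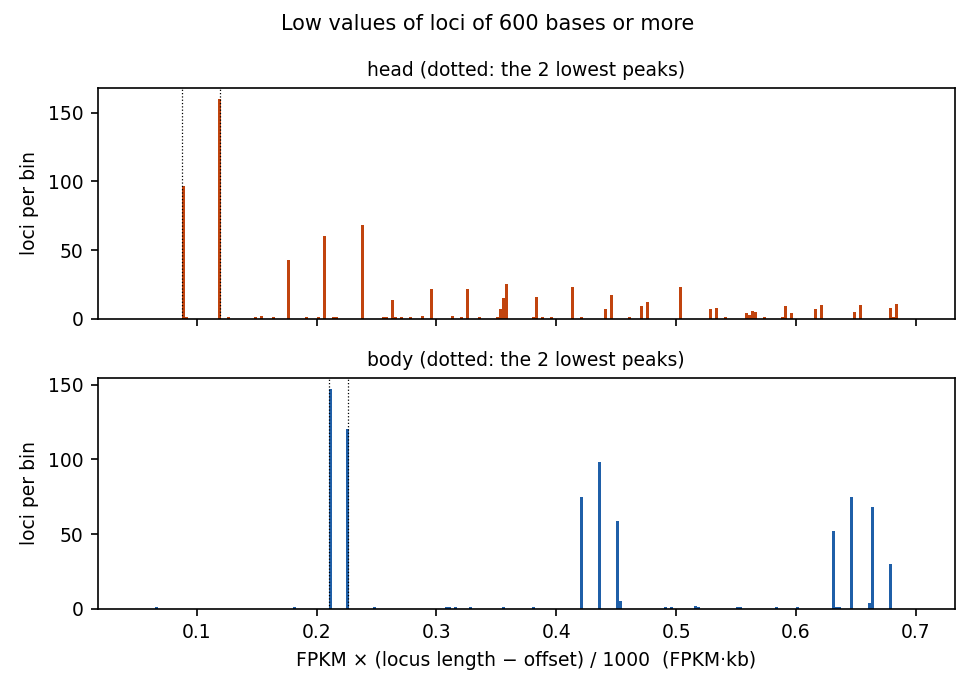
Number of loci per bin (y axis) against FPKM multiplied by locus length less an offset, in FPKM·kb (x axis), for loci of 600 bases or more with a value above 0, in head and in body. The dotted lines mark the 2 lowest peaks, at 0.0882 and 0.119 in head and at 0.210 and 0.226 in body, and the other peaks lie at their sums.

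Most loci were transcribed in both tissues, at levels that were only loosely related. The median locus had 9.22 FPKM in head (quartiles 3.99 and 24.3) and 11.0 FPKM in body (quartiles 3.60 and 35.8). At or above 1 FPKM there were 17539 loci in head and 17959 in body. Across loci, which are not independent replicates, Spearman's rho between the tissues was 0.345 and Pearson's r of log2(FPKM + 1) was 0.456. Of the 19853 loci at 1 FPKM or more in either tissue, 8800 (44.3%) differed by less than 2-fold on the log2(FPKM + 1) scale. The median difference, head over body, was 0.06 on that scale, with quartiles of -1.22 and 1.14. Equalising the upper quartiles of the tissues moved this median to 0.55, and among loci at 10 FPKM or more in either tissue it was -0.33, so the sign of small differences depends on these choices.

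In the authors' deposited table, 4637 of 19061 tested loci (24.3%) differed between head and body at a q of 0.05, and these are the loci termed called below. Body was the higher tissue for 2782 of them (60.0%) and head for 1855 (40.0%). Among called loci above 0 in both tissues, the median fold was 4.59 for the 1462 loci higher in body and 5.64 for the 1035 loci higher in head. The tissue with more calls changed with level, and in part with loci listed at 0. Where the higher tissue had 3 to 10 FPKM, 550 loci were called higher in head and 295 in body. Where it had 10 to 30 FPKM, 519 were called higher in head and 662 in body. Where it had 100 to 1000 FPKM, 271 were called higher in head and 731 in body. Above 1000 FPKM the numbers were 139 and 262. Counting only loci above 0 in both tissues, the calls higher in head and in body were 80 and 26 at 3 to 10 FPKM, 306 and 236 at 10 to 30 FPKM, 268 and 443 at 30 to 100 FPKM, 245 and 520 at 100 to 1000 FPKM, and 136 and 237 above that.

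**Figure D2:**
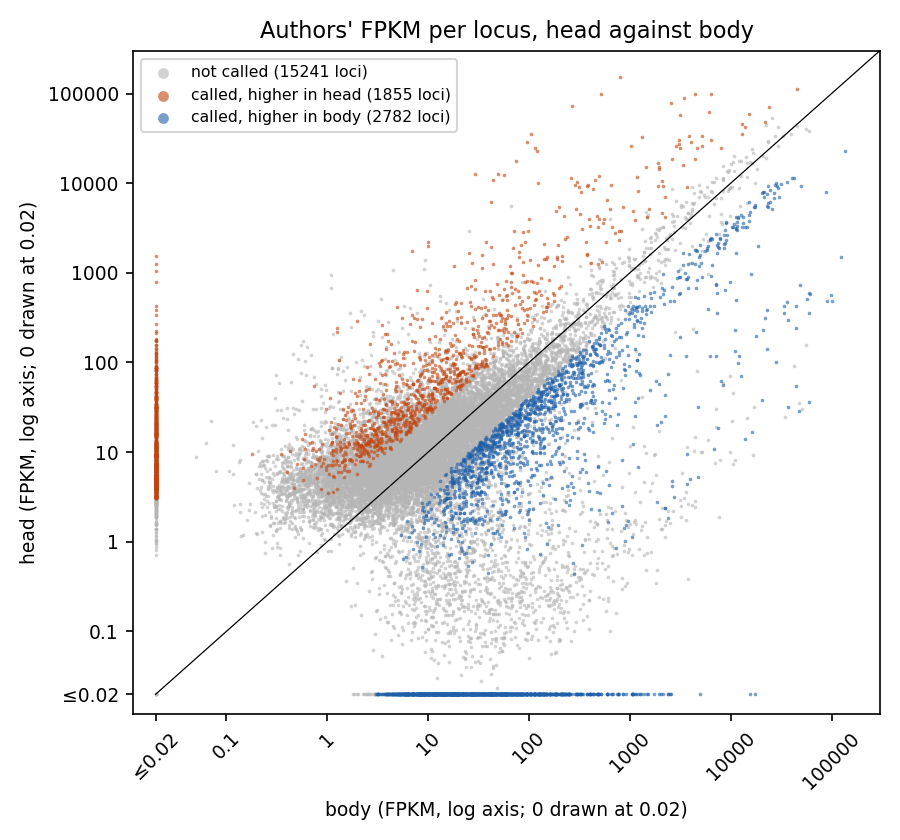
FPKM in head (y axis) against FPKM in body (x axis) for all 19878 loci, both on log axes, with 1 point per locus and values of 0 drawn at 0.02. Grey points were not called, orange points (1855) were called higher in head and blue points (2782) higher in body. The line marks equal levels, and the points on the left and lower edges are listed at 0 in one tissue.

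Nearly as many calls came from loci listed at 0 in one tissue as from loci measured in both. The authors' deposited table calls 1320 loci that are listed at 0 in head and 820 that are listed at 0 in body, together 46.2% of all calls. Of the tested loci listed at 0 in head, 99.5% were called, and of those listed at 0 in body, 97.4%, against 14.8% of the 16893 tested loci above 0 in both. These groups differed in level. The loci at 0 in head had a median of 27.4 FPKM in body (quartiles 11.8 and 69.6), and the loci at 0 in body had a median of 8.36 FPKM in head (quartiles 5.05 and 19.5). The fragment steps allow a limit for loci of 600 bases or more. At the level measured in body, the median of the 701 called loci at 0 in head would have had 144 fragments in the head libraries. With a limit of 3 fragments over both libraries for a value of 0, the median locus was at least 48.0-fold lower in head, and 659 of the 701 loci were at least 10-fold lower. The 294 loci at 0 in body would have had a median of 14.4 fragments at the head level, which gives a median bound of at least 4.81-fold, and 80 of them reached 10-fold. These limits cover counting error only.

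The loci named here are the 2 per direction with the largest fold among called loci above 0 in both tissues, with at least 10 FPKM in the higher one. XLOC_013050, on bases 1 to 248 of contig TRINITY_DN12850_c1_g1_i1, had 12516 FPKM in head and 29.0 FPKM in body. Its log2 ratio, on the log2(FPKM + 1) scale, was 8.70, and its q in the authors' deposited table was 0.00467. XLOC_011439, on bases 19 to 223 of TRINITY_DN12511_c0_g1_i5, had 35708 FPKM in head and 106 FPKM in body, a log2 ratio of 8.39 with a q of 0.00041 in the authors' deposited table. XLOC_004017, on bases 1 to 229 of TRINITY_DN10969_c0_g5_i6, had 28.7 FPKM in head and 47991 FPKM in body. Its log2 ratio was -10.66, and its q of 0.0490 in the authors' deposited table lay just under the threshold. XLOC_010914, on bases 1 to 278 of TRINITY_DN12418_c2_g2_i3, had 36.4 FPKM in head and 59682 FPKM in body, a log2 ratio of -10.64 with a q of 0.00041 in the authors' deposited table. These 4 loci are 205 to 278 bases long, close to the offset of about 200 bases in the fragment steps, and FPKM of such short loci divides by a very small effective length. 

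The chance of being called did not rise steadily with the size of the difference. Among loci with at least 10 FPKM in the higher tissue and above 0 in both, the authors' deposited table calls 61.9% of those 4 to 8 times higher in body, 23.6% of those 32 to 64 times higher and 7.57% of the 436 loci at least 256 times higher. In the head direction the share did not fall steadily. It was 45.1% at 4-fold to 8-fold, 44.6% at 8-fold to 16-fold, 53.6% at 16-fold to 32-fold, 43.9% at 32-fold to 64-fold, 20.5% of 39 loci at 64-fold to 128-fold, 43.8% of 32 loci at 128-fold to 256-fold and 45.5% of 11 loci at 256-fold or more. At 32-fold or more, 191 of 1124 loci were called. The 933 that were not comprise 841 loci higher in body and 92 higher in head. The number of fragments in the lower tissue went with the call. Among loci of 600 bases or more with at least 10 FPKM in body, 478 of 482 loci with 0 fragments in head were called. None of the 212 loci with 1 fragment was called (exact 95% Clopper-Pearson upper limit 1.72%), nor any of the 127 loci with 2 fragments (upper limit 2.86%). In the opposite direction, 56 of 57 loci with 0 fragments in body were called, none of 19 with 1 fragment (upper limit 17.6%) and none of 27 with 2 fragments (upper limit 12.8%).

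**Figure D3:**
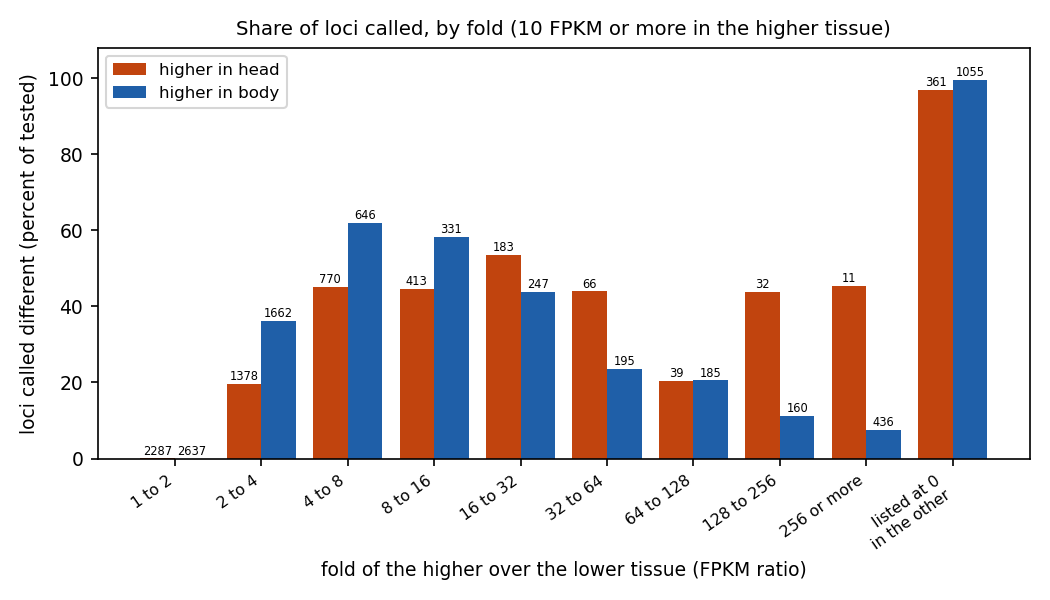
Percent of tested loci called different (y axis) by fold of the higher over the lower tissue (x axis), for loci with at least 10 FPKM in the higher tissue. Bars are coloured by the higher tissue and the number above each bar is the number of tested loci. In the body direction the share falls from 61.9% at 4-fold to 8-fold to 7.57% at 256-fold or more, and is 99.6% for loci listed at 0 in head.

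By FPKM, the lists of the 10 highest loci differed between head and body, while longer lists overlapped. The 10 loci with the highest FPKM in head shared no member with the 10 highest in body. Their median length was 173 bases in head and 268 bases in body, and FPKM of such short loci divides by a very small effective length. Whether lists of 10 differ among loci of at least 500 bases was not tested. The lists of 100 shared 32 loci, against 0.503 for independent lists. The lists of 1000 shared 599 loci, against 50.3. Of the 100 most abundant loci in head, 53 were called higher in head, and of the 100 most abundant in body, 65 were called higher in body. These 100 loci held 62.9% of the summed FPKM in head and 54.9% in body. Most of that signal lay in short loci, since the 2055 loci under 300 bases (10.3% of loci) held 67.4% of the summed FPKM in head and 57.7% in body. Among loci of at least 500 bases, the lists of 100 shared 52 loci, 32 of the head list were called higher in head, and 60 of the body list were called higher in body.

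Assembled variants of one gene mostly went the same way. The loci came from 15437 Trinity genes, the assembler's groups of related contigs, of which 3041 had more than 1 locus. Called loci belonged to 3970 Trinity genes, 2345 with calls higher in body only, 1590 higher in head only and 35 with calls in both directions. Of 910 pairs of called loci from one Trinity gene on different contigs, 863 had the same higher tissue and 47 (5.16%) had opposite ones, against 48.0% for random pairs of called loci. The pairs are not independent, since a Trinity gene with more called loci adds more pairs. The 48.0% holds for independent loci, and variants of one gene may share reads, so it is no matched baseline. Pairs in opposite directions included a locus listed at 0 in 51.1% of cases and pairs in one direction in 51.4%. Levels of variants that share reads are uncertain, as are those of 140 loci, 13 of them called, that overlap another locus of their contig.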

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

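The count of 4637 called loci stayed within 1.5 times under a q under 0.01 (3473), with q recomputed (4637), with a filter of 1 FPKM (4637), with a minimum of 2-fold (4636), and, chosen after seeing the data, in loci of at least 500 bases (3212) and with 1 locus per Trinity gene (3609). Leaving out loci listed at 0 in one tissue moved it to 2497, with 1035 higher in head and 1462 higher in body, by construction. In loci of at least 500 bases, 1197 were called higher in head. Called loci listed at 0 fell there to 404 higher in head and 850 higher in body. Fewer loci were counted, but the percent of tested loci listed at 0 also fell with length, so number alone does not set this fall. Body remained the tissue with more calls under each of these settings. Rescaling to equal upper quartiles or to equal sums (0.56 and 0.39 in log2), added after seeing the data, could turn no called locus, since the smallest fold among them was 1.92, so it does not test the directions. The median difference of all loci, 0.0626 head over body, was 0.0691 with a pseudocount of 0.1, 0.0434 with 5, 0.55 with equal upper quartiles, 0.28 after rescaling to TPM and -0.33 among loci at 10 FPKM or more; its sign therefore depends on the level of the loci, and what else sets it was not tested. XLOC_004017 (q = 0.0490 in the authors' deposited table) was not called at a q of 0.01, and the other 3 named loci were. Pairs of one Trinity gene in opposite directions numbered 23 at that q and 23 without loci listed at 0. The 933 loci of 32-fold or more that were not called ranged from 701 to 1157 over 5 alternatives, all added after seeing the data. No paired analysis was possible because the table carries 1 value per tissue and no replicate columns. For the same reason leaving out replicates, a count model and its normalization could not be run, and the gene lists gave no result because no locus has a name. Depth limits loci at 0 in body more than those at 0 in head, as head was 2.15 times as deep.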

Other observations

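Loci listed at a small part of their level in the other tissue were more common in the body direction. Of the 10398 loci at 10 FPKM or more in body, 2031 (19.5%) were listed at less than 1/32 of that level in head, 976 above 0 and 1055 at 0, and these are termed restricted to body. Of the 9402 loci at 10 FPKM or more in head, 509 (5.41%) were listed at less than 1/32 in body, 148 above 0 and 361 at 0. A value of 0 does not by itself show a level under 1/32. With a floor of 3 fragments, 409 of the 482 loci of 600 bases or more at 0 in head were at least 32-fold lower, but only 12 of the 57 at 0 in body, and no bound was computed for the shorter loci (573 at 0 in head and 304 at 0 in body). With equal upper quartiles, an alternative added after seeing the data, the totals were 1914 and 602. The body set had a median of 55.4 FPKM and a median length of 691 bases, and the head set 31.1 FPKM and 349 bases. The authors' deposited table calls 1186 of the body set and 406 of the head set.

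Among long, abundant loci, levels under 1/256 in the other tissue were also more common in the body direction, with no gap in the counts at 1/32. Of 215 loci with at least 500 FPKM in body and 600 bases or more, 54 were under 1/256 of that level in head, 17 lay between 1/256 and 1/32, 19 between 1/32 and 1/8, and 125 above that. Of 95 such loci in head, 1 was under 1/256 in body and 4 lay between 1/256 and 1/32. Among loci of any length, 301 had at least 1000 FPKM in both tissues, a set not separate from those above. Of these, 141 lay within 2-fold, 53 were over 2-fold higher in head, and 107 from 98 Trinity genes were over 2-fold higher in body with a median fold of 3.17 and quartiles of 2.72 and 3.84. The 53 loci came from 38 Trinity genes, with a median fold of 4.86 and quartiles of 3.12 and 8.91. The authors' deposited table calls 94 of the 107 loci and 45 of the 53.

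Of the tests below, those of assembled variants, of the detection limit over both tissues, of restricted transcription, of 1 fragment in body and of the summed share were set out before their results were seen. The tests of 1 fragment in head, of the detection limit by tissue and length, of the level in the higher tissue and of the median share were chosen after. Of 2 earlier tests of that level, one set out before was dropped because the choice of loci by fold sets its outcome, and one chosen after was dropped because its loci were already known to hold no calls.

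The largest differences above 0 were mostly not called. A candidate explanation for part of them is that 1 fragment in the lower tissue fixes the deposited p whatever the other tissue holds. Of loci at 1 fragment in head and 10 FPKM or more, up to 726 FPKM, in body, 0.0% were called and p took 3 values from 0.205 to 0.247, and of loci at 1 fragment in body 0.0% were called as well. A low level in the higher tissue stays open. Of the 561 loci of 32-fold or more at 100 FPKM or more, 29.4% were called (exact 95% interval 25.7% to 33.4%). The share rose from 1.28% at 10 to 30 FPKM to 52.0% above 1000 FPKM. Among loci of 32-fold or more, a lower level also leaves fewer fragments in the lower tissue. This rise therefore cannot separate level from fragment number. How p was computed for such loci is not given in the sources used here, and the hypothesis was tested on the same table that raised it.

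For the 2140 called loci listed at 0 in one tissue, reads lost to other assembled variants could be checked only within a Trinity gene. In 16.6% of these loci another locus of the same Trinity gene had 1 FPKM or more in the tissue at 0. A locus alone in its Trinity gene could not be counted, and 3041 of 15437 Trinity genes had more than 1 locus. How many of the 2140 loci had another locus in their Trinity gene was not counted. The 16.6% can therefore not be set against the loci open to such a loss. Reads lost to contigs outside the Trinity gene also remain possible. A level near the detection limit is argued against for the 701 loci of 600 bases or more at 0 in head, of which 94.0% were at least 10-fold lower in head with 0 taken as 3 fragments. It may account for loci at 0 in body, where the share at 0 fell with level from 8.06% at 3 to 10 FPKM to 0.429% above 1000 FPKM. Of the called loci at 0 in body, 91.8% lay below the median of loci called in the same direction and above 0 in both. That comparison cannot decide, because the calling largely sets it. Loci at 0 were called at nearly any level, whereas none of 385 loci at 1 or 2 fragments in the lower tissue was called. A level near the detection limit stays open for the 619 shorter loci at 0 in head and for both tissues together. Of the shorter loci, 94.2% lay below the median of loci of those lengths (70.1% below that of all lengths), and 84.5% did so in both tissues together. The calling likewise largely sets these shares. In the shorter loci the share at 0 rose from 3.08% at 3 to 10 FPKM to 14.9% at 100 to 1000 FPKM and was 4.33% above. Restricted transcription also stays open. At 10 FPKM or more in the higher tissue, there were 0.136 called loci of 32-fold or more above 0 per called locus at 0 (1401 loci). That ratio was 0.802 when loci above 0 that were not called were counted as well.

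Loci restricted to body were chosen for a head level under 1/32 of body, so a low head level is no finding. In those of 600 bases or more, the median head level was 0.129% of body at 100 to 300 FPKM, 0.129% at 300 to 1000 FPKM and 0.135% above 1000 FPKM (32 loci), but 0.0% at 10 to 30 FPKM (440 loci, 59.1% at 0) and 0.151% at 30 to 100 FPKM, where a median of 495 fragments at the body level makes the value about 1 fragment or less, and the summed share ran from 0.309% to 1.17% over these classes. At 100 to 300 FPKM the median was 1429 fragments at the body level, and 18.3% of loci were at 0 in head. The 0.129% of that class therefore also rests on few fragments. A single share at the summed value of 0.852% is argued against, because it missed the percent of loci at 0 by up to 39.3 points. That sum leans on the most abundant loci, so the miss does not exclude a common share at another value. The restricted loci were not variants of few Trinity genes, with 1646 Trinity genes for 2031 loci (81.0 per 100), near the 15437 for all 19878 loci. Variants of one gene split over several Trinity genes would escape this count, so they stay open. The median share of the most abundant loci predicted 49.5%, 17.4% and 2.70% of loci at 0 in the classes from 30 to 1000 FPKM against 43.7%, 18.3% and 6.98% observed, but missed the class of 10 to 30 FPKM by 18.1 points, so carry-over for most of these loci remains undecided. The tissues of the body that the head lacks, or another organism in the body, stay open and untested.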
